A study of Mus musculus with 4 samples.

How the data were processed

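RNA was measured in frozen hippocampus of mice at postnatal day 30, from 2 conditional mutants of Atp6ap2 and 2 wild-type mice on the C57BL/6N background. Per the labels' protocols, ribosomal RNA was removed from total RNA, complementary DNA was made from fragmented RNA with random primers, and the dUTP method kept the strand. The 4 libraries shared a lane and were read from a single end. Per the submitters' processing notes, GSNAP and DESeq2 were used with the mouse build mm9, with no versions or roles given. The read counter, its strand setting and the annotation version are not given in the sources used here. No coordinates are printed, because the reference genome used here for names is another build.

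The authors deposited a table of 31315 transcript records with 23466 gene symbols and 30380 distinct RefSeq accessions, with 1 value for each library and 1 p-value for each record. The deposited values are signal, aligned bases summed over a transcript and divided by 1 scaling factor per library. In each library 100% of the values were whole multiples of a single step, within 0.05 of a step, and low values piled up at 42, 84 and 126 steps, so 1 read contributed 42 bases. The values are therefore neither counts of reads nor normalised for transcript length, and a read that several transcripts share can be in each of them. The p-value column of the deposited table is named after DESeq, and its header does not say whether it was adjusted. Among 16515 records with different values and a mean above 100 read equivalents, 140 repeated a p-value of another record, as unadjusted p-values would do rarely, and a Benjamini-Hochberg adjustment was applied to it here.

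Each deposited value was divided by 42 and is called a scaled read equivalent. A gene was represented by the transcript with the highest mean over the 4 libraries. Genes with at least 1 read equivalent in 2 or more libraries were tested on log2(read equivalents + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2 scale, which understates the change of genes with few reads. The division by 42 was decided after the unit was known and before any test was run. The edgeR test planned for counts and its planned DESeq2 alternative need counts and were not run, and limma was the planned test for normalised values. The group was the only term of the model, since replicate numbers are not shared between the groups. Python 3.11.15 and matplotlib 3.10.9 were used for reading the table and for plots.

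Gene lists for cell types, brain regions and pathways were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 between genes, and with camera at an estimated correlation and with fry as alternatives, adjusted over the 32 lists with at least 3 measured genes. The genes named were set by a rule written before the data were examined. The rule takes Atp6ap2, the 10 higher and 10 lower genes with the largest fold change among those that passed with both mutants beyond both wild-types, and up to 4 members of each list with the smallest p-values. If fewer than 5 genes pass, it adds the 5 higher and 5 lower genes with the smallest p-values, and Apold1, which passed, counts among the 5 higher. Not all genes that the rule names are reported here. Other genes are said to come from the authors' deposited table or to have been chosen after their values were seen.

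Before scaling, the libraries held 18339838 (wild-type 11), 10023033 (wild-type 73), 18328405 (mutant 38) and 17543464 (mutant 39) read equivalents over genes. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 9.06 and 20.5, so all 4 were counted as separate samples. The labels speak of samples and do not say how they were obtained from separate animals, so p-values measure the spread between these samples. With 2 against 2 libraries a two-sided exact permutation test cannot give a p below 0.333, and both mutants lie beyond both wild-types by chance in 33.3% of genes.

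The fit was tested on simulated data for the mutant against wild-type comparison, with 200 changed genes in each of 5 draws. Data were drawn from the real means and depths and from the moderated spreads of the fits. The changed genes were drawn only from genes with a mean signal well above the filter. The shares found therefore do not cover genes with few reads. Apart from the choroid plexus difference, genes varied independently, and sampling noise was added to spreads that already held it. With a choroid plexus difference between libraries as large as the real one, it found 50.4% of the genes changed 2-fold and 87.4% of those changed 4-fold among 17750 genes, with a mean of 0 false calls. Without such a difference it found 69.4% and 94.6% among 17720 genes, with a mean of 16.2 false calls. With no gene changed and no choroid plexus difference, a mean of 4.6 genes of 17740 were called. A fit with the choroid plexus level as a covariate, again with no gene changed, called a mean of 1 gene of 17750 where libraries differed in choroid plexus and 42.4 of 17730 where they did not. With 200 genes changed, the covariate fit found 80.4% of the 2-fold and 99.2% of the 4-fold changes among 17760 genes with a mean of 13 false calls where libraries differed in choroid plexus. Where they did not, it found 58.6% and 81.4% among 17740 genes with a mean of 53 false calls. Draws without a choroid plexus difference used the spreads of the group-only fit, which hold the real difference as noise. Draws with it used the spreads of the covariate fit. The contrast between the draws therefore does not measure the effect of a choroid plexus difference alone. Alternatives covered the scaling between libraries, the filter, the variance prior, the pseudocount, limma-voom, the threshold, the choice of transcript, the choroid plexus level as a covariate and leaving out each library in turn.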

Results

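The data comprised 4 libraries of ribosome-depleted hippocampal RNA from mice at postnatal day 30. Mutants 38 and 39 carried a conditional Atp6ap2 allele with Camk2a-Cre, a recombinase driven in forebrain excitatory neurons, and wild-types 11 and 73 were the controls. Atp6ap2, the prorenin receptor, is an X-linked accessory subunit of the vacuolar proton pump. The titles of the mutants read ko, taken here as knockout, and their condition field reads conditional het, taken here as conditional heterozygote. Depth ranged from 10023033 read equivalents over genes in wild-type 73 to 18339838 in wild-type 11, and between 18281 and 19029 genes had signal. Transcripts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were read in every library. Ddx3y had 1168 ± 111 scaled read equivalents in wild-type and 1198 ± 53.4 in mutant (SD, n = 2 each), while Xist had between 13.6 and 46.2. These values read as male samples. A male cannot be heterozygous for an X-linked gene, so the field, if it means heterozygote, cannot describe Atp6ap2 itself. The comparison asked which hippocampal transcripts differ when Atp6ap2 is targeted in excitatory neurons, for a gene that the series title links to intellectual disability and parkinsonism.

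Atp6ap2 itself had 2312 and 2637 scaled read equivalents in wild-types 11 and 73 and 2551 and 2522 in mutants 38 and 39. Its log2 fold change was 0.04 ± 0.10 (SE, n = 2 per group; 95% interval -0.21 to 0.29; limma adjusted p = 0.991). In the authors' deposited table its p was 0.800. Atp6ap2 was planned as a check on the labels, and it showed no drop in the mutants. The value sums the whole transcript, including exons outside any deleted part and RNA of cells without Cre. Exons were not examined one by one, so loss of the targeted gene was neither shown nor excluded in these libraries. The 21 other subunits of the vacuolar proton pump had a median log2 fold change of 0.02, a mean of -0.02 and a camera adjusted p of 0.822. Atp6v0c, a proton-conducting ring subunit, had -0.40 ± 0.18, and Atp6v0a1 had -0.32 ± 0.18 (SE, n = 2 per group), both with a limma adjusted p of 0.989.

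Apold1, an early response gene of blood vessel endothelium, rose from 239.9 ± 0.771 to 1419 ± 207 scaled read equivalents in the mutants (SD, n = 2 each). That is a log2 fold change of 2.55 ± 0.14 (SE; 95% interval 2.23 to 2.87; limma adjusted p = 0.00569). It was the only gene of 18127 that passed, and 0 genes passed in the lower direction, while 396 higher and 318 lower genes had an unadjusted p below 0.05. The next genes by p-value did not pass. On the higher side, Cyr61, a secreted matrix protein induced within minutes of stimulation, had 164 ± 1.63 in wild-type and 961 ± 398 in mutant (SD, n = 2 each; log2 fold change 2.47 ± 0.26 SE, limma adjusted p = 0.123). Akap12, a scaffold for protein kinase A, had a log2 fold change of 1.43 ± 0.16, the small nucleolar RNA Snora81 had 1.16 ± 0.12, and the linker histone gene Hist1h1e had 1.01 ± 0.12 (SE, n = 2 per group). On the lower side, Dio3, the enzyme that inactivates thyroid hormone, had 107 ± 13.2 in wild-type and 10.8 ± 2.57 in mutant (SD, n = 2 each; log2 fold change -3.20 ± 0.32 SE, limma adjusted p = 0.123). Vgll3, a transcription cofactor, had -2.38 ± 0.31, Arc, a synaptic activity-regulated gene, had -1.06 ± 0.13, Col6a1, a chain of collagen VI, had -0.95 ± 0.14, and Clk1, a kinase of splicing factors, had -0.84 ± 0.09 (SE, n = 2 per group). The number of genes that passed depended on single libraries: 37 without wild-type 11, 8 without mutant 38, 7 without mutant 39 and 1 without wild-type 73, Apold1 among them each time. It was 12 with a robust variance prior, and 0 on values left in bases, where Apold1 had an adjusted p of 0.0614.

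**Figure D1:**
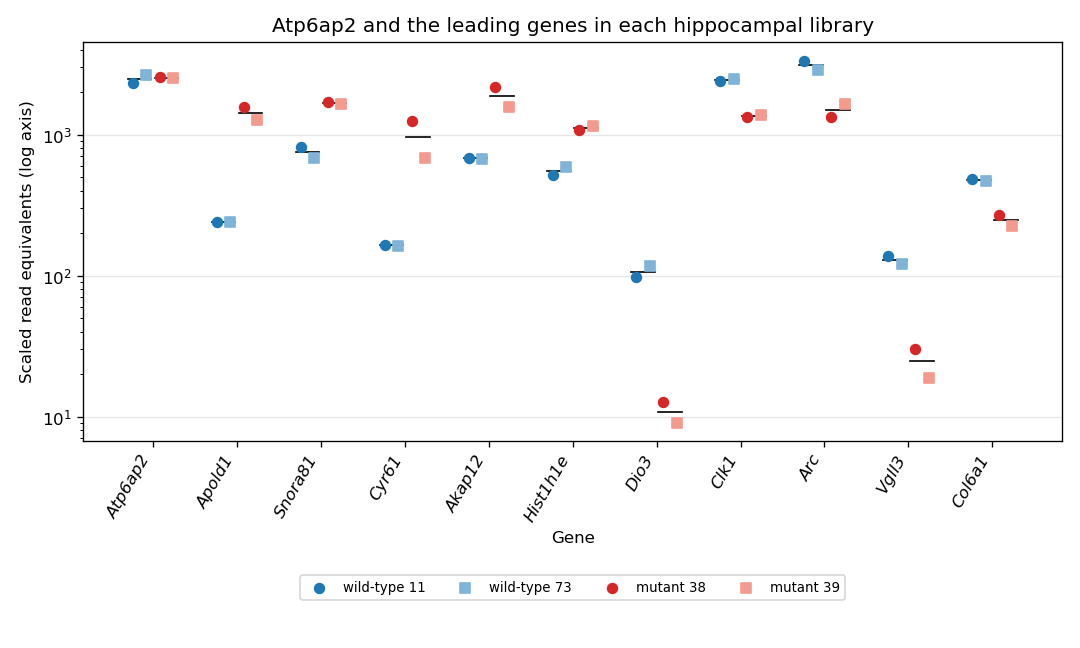
Scaled read equivalents (log axis) of Atp6ap2 and of the 5 higher (Apold1 among them) and 5 lower genes with the smallest p-values, with 1 point per library and a black bar at each group's mean. The Apold1 points lie at 239 and 240.5 in wild-type and at 1565 and 1273 in mutant, and Atp6ap2 lies between 2312 and 2637 in all 4 libraries.

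In the authors' deposited table, 544 transcript records had a p below 0.05, of which 325 were higher and 219 lower in the mutant. After the Benjamini-Hochberg adjustment made here, 61 records of 45 genes remained, 30 genes higher and 15 lower. All 45, measured in the same libraries, had the same direction and an unadjusted p below 0.05 in the limma fit, and all had both mutants beyond both wild-types. Apold1 (p = 2.59e-45), Cyr61 (p = 5.18e-20) and Akap12 (p = 1.15e-15) led the authors' deposited table. The genes below were taken from that list and did not pass in limma. Among the higher ones were the transcription factor gene Maff (log2 fold change 2.37 ± 0.28), the ephrin receptor gene Epha2 (2.11 ± 0.28), the endothelin gene Edn1 (1.48 ± 0.27), Zfp36, which encodes a protein that destabilises messenger RNA (1.38 ± 0.19), the kinase gene Sgk1 (0.91 ± 0.13) and the glucose transporter gene Slc2a1 (0.72 ± 0.12; SE, n = 2 per group). Among the lower ones were the receptor gene Trhr (-2.27 ± 0.37), Tnfrsf25 (-1.68 ± 0.28), the small matrix proteoglycan gene Dcn (-1.39 ± 0.28), Crym, which encodes a thyroid hormone-binding protein (-0.73 ± 0.19), and the prostaglandin synthase gene Ptgds (-0.48 ± 0.10; SE, n = 2 per group).

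Choroid plexus markers divided each group. Ttr, the thyroxine carrier made in choroid plexus epithelium, had 41492 and 70079 scaled read equivalents in wild-type 11 and mutant 38, against 2562 and 1749 in wild-type 73 and mutant 39. All 17 markers were higher in the first pair of libraries than in the second, by 2.78-fold to 24.2-fold between the nearest libraries. Between mutant and wild-type the list's median log2 fold change was 0.18 (camera adjusted p = 0.744), and 0 of its members had an unadjusted p below 0.05. Within the pair low in these markers (wild-type 73 and mutant 39), the log2 fold change was 2.40 for Apold1, 2.05 for Cyr61, 1.21 for Akap12, -3.55 for Dio3 and -0.81 for Arc. Within the pair high in them (wild-type 11 and mutant 38) it was 2.70, 2.90, 1.66, -2.85 and -1.32 for the same genes in that order. For each of these genes both mutants lay beyond both wild-types. The shared direction of the pairs follows from that and is no separate check. With the choroid plexus level as a covariate, chosen after seeing the data and leaving 1 residual degree of freedom, 80 genes passed, 56 higher and 24 lower, and 44 of them were among the 45 of the authors' deposited table.

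**Figure D2:**
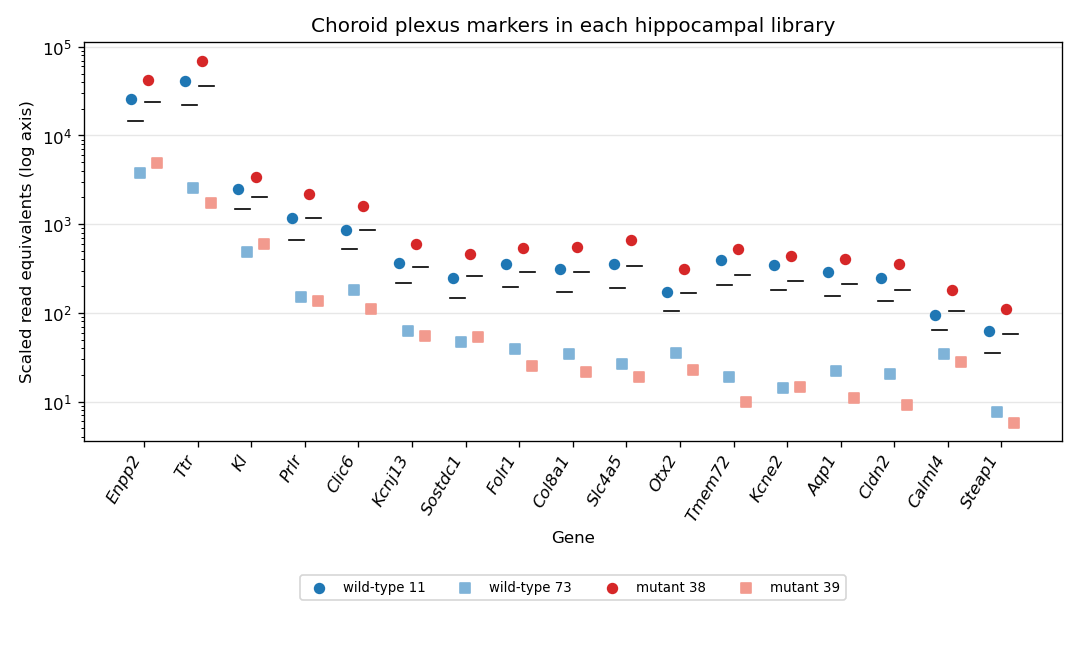
Scaled read equivalents (log axis) of the 17 choroid plexus markers, with 1 point per library and a black bar at each group's mean. For every marker, wild-type 11 and mutant 38 lie above wild-type 73 and mutant 39, as for Ttr with 41492 and 70079 against 2562 and 1749.

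Of the 32 gene lists tested, 3 rose and 1 fell with the preset correlation. Markers of myelinating oligodendrocytes rose with a median log2 fold change of 0.44 (camera adjusted p = 5.05e-12, but 0.913 with an estimated correlation), and 12 of 16 were higher in both mutants than in both wild-types. The myelin genes Mal (0.45 ± 0.13), Mog (0.43 ± 0.14), Mobp (0.47 ± 0.16) and Mag (0.39 ± 0.14; SE, n = 2 per group) were its members with the smallest p-values. Red blood cell genes rose by a median of 0.47 (camera adjusted p = 5.02e-06, but 0.913 with an estimated correlation), with 5 of 7 higher in both mutants. Among them were the haem synthesis gene Alas2 (0.49 ± 0.20) and the globin gene Hbb-bs (0.88 ± 0.33, SE, n = 2 per group). The values of Hbb-bs were nearly those of Hbb-b1, a record of near-identical sequence, so that globin genes are uncertain one by one. The count of 5 of 7 can therefore hold the same reads more than once. With 1 gene kept of each set with the same values, the blood list had a camera adjusted p of 0.000921 at the preset correlation. Thalamus markers rose by a median of 0.81 (camera adjusted p = 1.95e-05, but 0.913 with an estimated correlation), with 2 of 8 higher in both mutants. Slc17a6, the vesicular glutamate transporter of thalamic neurons, had 394 ± 19.7 in wild-type and 868 ± 121 in mutant (SD, n = 2 each) and was the only member to pass adjusted over the list alone (adjusted p = 0.000582, limma). Prkcd had 1841 in mutant 38, 465 in mutant 39 and 405 to 499 in wild-type. Dentate granule cell markers fell by a median of 0.25 (camera adjusted p = 0.0267, but 0.913 with an estimated correlation), and 1 of 9, C1ql2, was lower in both mutants (-0.33 ± 0.12 SE, n = 2 per group). The calls of the 4 lists were thus made with camera at the preset correlation and not at an estimated one. The size of the correlation alone does not account for that loss. Striatum markers had an estimate of -0.063, below the preset value, yet their unadjusted camera p rose from 0.038 to 0.16. For p53 and apoptosis genes, with an estimate of -0.049, it rose from 0.12 to 0.23. The adjusted p of 0.913 therefore cannot decide whether the 4 lists changed.

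The medians of the 4 lists also depended on single libraries and on the choroid plexus pairs. The oligodendrocyte median was 0.20 without wild-type 73, 0.36 without mutant 38, 0.54 without mutant 39 and 0.64 without wild-type 11. It was 0.56 and 0.26 within the pairs low and high in choroid plexus markers. The blood median was 0.17 without wild-type 73, 0.29 without mutant 39, 0.65 without mutant 38 and 0.78 without wild-type 11. It was 0.96 and 0.06 within these pairs. The thalamus median was 0.03 without mutant 38 (camera adjusted p = 0.178), and 0.10 and 1.22 within the pairs. The dentate median was -0.34 without wild-type 11 (adjusted p = 0.0899), -0.16 without wild-type 73, -0.13 without mutant 38 and -0.05 without mutant 39 (adjusted p = 0.204), and -0.17 and 0.06 within the pairs.

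**Figure D3:**
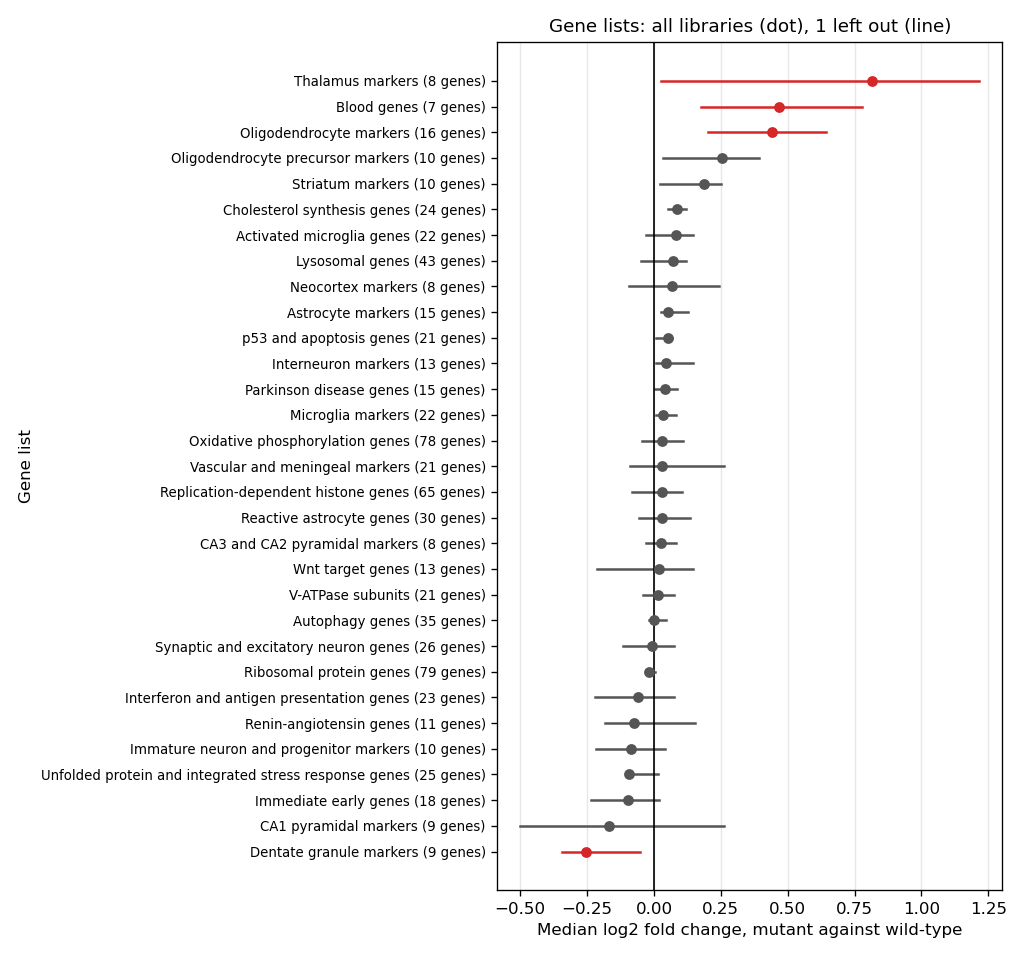
Median log2 fold change (mutant against wild-type) of 31 gene lists, with the number of measured genes, as a dot for all libraries and a line from the lowest to the highest median with each library left out in turn. The 4 lists past the camera threshold at the preset correlation are red, with medians of 0.81 for thalamus, 0.47 for blood, 0.44 for oligodendrocyte and -0.25 for dentate granule cell markers, and the choroid plexus list is not drawn.

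Immediate early genes went both ways. Of 18 measured, 3 higher and 4 lower members passed adjusted over the list alone, and 0 passed over all genes. The higher ones were Cyr61, the phosphatase gene Dusp1 (log2 fold change 0.95 ± 0.12) and the antiproliferative gene Btg2 (0.70 ± 0.14). The lower ones were Arc, Npas4 (-0.66 ± 0.17), Nr4a3 (-0.52 ± 0.15) and Junb (-0.45 ± 0.12, SE, n = 2 per group). Fos, a widely used activity marker, had 405 ± 0.113 in wild-type and 418 ± 117 in mutant (SD, n = 2 each). The list's median was -0.10 and its mean 0.05, with a camera adjusted p of 0.604. Among 25 unfolded protein and integrated stress response genes, Atf3 alone passed adjusted over the list alone (2.16 ± 0.32), while Xbp1 had -0.30 ± 0.11. The list's median was -0.09 and its mean 0.02 (camera adjusted p = 0.796). Among 21 p53 and apoptosis genes, the cell cycle inhibitor gene Cdkn1a alone did so (1.56 ± 0.29; SE, n = 2 per group), and the list's median was 0.05 (camera adjusted p = 0.346). Of 65 replication-dependent histone genes, whose messages lack a poly(A) tail, the linker histone genes Hist1h1e and Hist1h1c (0.92 ± 0.11) passed adjusted over the list alone. The histone list's median was 0.03 (camera adjusted p = 0.393), and fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.00125.

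Pathway lists, among them those close to the function of Atp6ap2, did not pass with all 4 libraries. Lysosomal genes had a median log2 fold change of 0.07 over 43 genes (camera adjusted p = 0.604), with Hexa at -0.27 ± 0.10 and Lgmn at 0.23 ± 0.10 (SE, n = 2 per group). The median of 35 autophagy genes was -0.00086 and their mean 0.02 (adjusted p = 0.720, limma's camera), with Gabarap at 0.23 ± 0.10. Renin-angiotensin genes had a median of -0.08 and a mean of 0.02 (adjusted p = 0.720, limma's camera), with the receptor gene Mas1 at -0.38 ± 0.13. Wnt target genes had a median of 0.02 with a camera direction of lower (adjusted p = 0.720), with Axin2 at -0.37 ± 0.13. Genes with variants that cause parkinsonism had a median of 0.04 (camera adjusted p = 0.611), with Pink1 at 0.19 ± 0.10. Cholesterol synthesis genes had a median of 0.09 (camera adjusted p = 0.0668), which ran from 0.052 without wild-type 11 to 0.12 without mutant 38. Of these 24 genes, 11 were higher in both mutants, among them Hmgcs1 at 0.30 ± 0.10 and Insig1 at 0.34 ± 0.13 (SE, n = 2 per group). Oxidative phosphorylation genes had a median of 0.03 (camera adjusted p = 0.574) and ribosomal protein genes a median of -0.02 with a mean of 0.04 (camera adjusted p = 0.956). Some abundant genes have little signal in the deposited values. Gapdh had 16.0 (wild-type 73) to 23.5 (mutant 38) scaled read equivalents, against 47567 (wild-type 11) to 53699 (mutant 39) for Actb. The cause, and whether ribosomal protein genes are affected too, was not tested.

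With all 4 libraries, neuronal lists other than the dentate and thalamus lists did not pass. CA1 pyramidal markers had a median of -0.17 (camera adjusted p = 0.219), which was -0.50 without mutant 39 (4.55e-08) and 0.26 without mutant 38 (0.0696). Within the pairs low and high in choroid plexus markers it was 0.17 and -0.43. Among these markers, Fibcd1 alone passed adjusted over the list alone, at 2271 ± 39.1 in wild-type and 1496 ± 147 in mutant (SD, n = 2 each; log2 fold change -0.60 ± 0.11 SE, adjusted p = 0.00705, limma). The median was 0.03 for CA3 and CA2 markers (camera adjusted p = 0.812), -0.01 for synaptic and excitatory neuron genes (0.574), 0.05 for interneuron markers (0.574) and -0.08 for immature neuron and progenitor markers (0.529). The interneuron median ran from 0.0065 without mutant 39 to 0.14 without wild-type 73. Neocortex markers had a median of 0.07 (camera adjusted p = 0.482). Striatum markers had a median of 0.19 (camera adjusted p = 0.201, fry's mixed adjusted p = 0.0222), which ran from 0.023 without mutant 38 to 0.25 without mutant 39. Penk, which encodes the enkephalin precursor, passed adjusted over the list alone (0.78 ± 0.16 SE, n = 2 per group, limma adjusted p = 0.0214).

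With all 4 libraries, glial and vascular lists other than the oligodendrocyte list did not pass either. Oligodendrocyte precursor markers had a median of 0.25 (camera adjusted p = 0.219), which ran from 0.034 without mutant 38 to 0.39 without mutant 39. The lineage factor gene Olig2 alone passed adjusted over the list alone (0.52 ± 0.11 SE, n = 2 per group). Of the 10 markers, 3 were higher and 2 lower in both mutants, Gpr17 among the lower (-0.29 ± 0.11 SE). The median was 0.05 for astrocyte markers (camera adjusted p = 0.244), 0.03 for reactive astrocyte genes (0.705), 0.03 for microglia markers (0.720) and 0.08 for activated microglia genes (0.720). Interferon and antigen presentation genes had a median of -0.06 (camera adjusted p = 0.303). Vascular and meningeal markers had a median of 0.03 (camera adjusted p = 0.720), and Dcn alone passed adjusted over the list alone, in the lower direction, with a log2 fold change of -2.03 within the pair low in choroid plexus markers and -0.76 within the pair high in them.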

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

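The alternatives on values in bases, on transcripts, on the choroid plexus covariate, on repeated values and on fry's mixed test were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, since the values are not counts. The log2 fold change of Apold1 lay between 2.40 and 2.70 and its adjusted p between 1.07e-08 and 0.0614 over 16 alternatives, and it missed the threshold on values in bases, where 0 genes changed and 0 were higher. With the robust variance prior 12 genes changed, 8 higher and 4 lower. With the choroid plexus covariate 80 changed, 56 higher and 24 lower. Leaving out each library gave 1 to 37 changed genes, 1 to 23 higher and 0 to 14 lower, with the lone library of a group assumed to vary like the others. The change of Atp6ap2 then ranged from -0.056 (without wild-type 11) to 0.13, and 4 to 11 gene lists passed. An estimated correlation and fry's directional test left 0 lists, and fry's mixed test 2. Over the other combinations of named genes and alternatives, 2572 kept direction and side of the threshold, 87 gained the threshold, 1 lost it and 24 changed sign, none of them past the threshold in either setting. For list medians these counts were 564, 19, 15 and 42, of which 3 passed in either setting: choroid plexus without wild-type 73 (-1.23) and without mutant 38, and vascular without mutant 38. With 1 library left out at a time, the choroid plexus median ran from -1.82 to 2.23, vascular from -0.091 to 0.26 and CA1 from -0.50 to 0.26. CA3 and CA2 ran from -0.029 to 0.083, immature neuron from -0.22 to 0.042, synaptic from -0.12 to 0.076 and neocortex from -0.094 to 0.24. Reactive astrocyte genes ran from -0.057 to 0.14, activated microglia from -0.031 to 0.14, interferon from -0.22 to 0.074 and immediate early genes from -0.23 to 0.018. V-ATPase subunits ran from -0.041 to 0.075, lysosomal genes from -0.048 to 0.12, autophagy from -0.018 to 0.045 and unfolded protein response from -0.099 to 0.015. Wnt targets ran from -0.21 to 0.15, renin-angiotensin from -0.18 to 0.15, ribosomal protein genes from -0.019 to 0.0055, oxidative phosphorylation from -0.046 to 0.11 and histone genes from -0.083 to 0.11. Among genes, Sostdc1 ran from -0.999 to 2.09, Enpp2 from -0.997 to 2.11, Kl from -0.90 to 1.63, Calml4 from -1.02 to 1.66 and Calb2 from -1.78 to 0.14. Nov ran from -1.05 to 0.055, Mpped1 from -0.62 to 0.049, Lct from -0.55 to 0.0051, Cpne4 from -0.065 to 0.28 and Cux2 from -0.028 to 0.52. Foxp2 ran from -0.19 to 1.13, Lef1 from -0.034 to 1.02, Ddx3y from -0.057 to 0.14, Uty from -0.13 to 0.033 and Kdm5d from -0.051 to 0.092. The other sign changes came with all 4 libraries. With the choroid plexus covariate the medians were -0.022 for choroid plexus, 0.0018 for autophagy, 0.0012 for synaptic and -0.016 for Wnt targets. The Wnt median was -0.00023 with the stricter filter and without shared genes, and the renin-angiotensin median 0.043 with no filter and on values in bases. V-ATPase subunits had -0.0016 with upper-quartile scaling, autophagy 0.0020 on mean transcripts and Kdm5d -0.0068 with limma-voom. For the counts that moved and for the changes of sign, the cause was not tested. Depth limits genes with few reads most in wild-type 73, at 10023033 read equivalents.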

Other observations

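The tests below on glucocorticoid-induced genes, tissue carry-over, depth, vessel cells and neuronal activity, the choroid plexus covariate and the use of the planned omission of mutant 38 to weigh the thalamus list were chosen after the result was seen. Genes known to be induced by glucocorticoids were looked at because Sgk1 and Tsc22d3 (log2 fold change 0.58 ± 0.10 SE, n = 2 per group) stood in the authors' deposited table. Among 8 others in none of the fixed lists, Plin4, a lipid droplet gene, had 0.71 ± 0.20, Mt2, a metallothionein gene, 0.38 ± 0.15, and Klf9, a transcription factor gene, 0.35 ± 0.09 (SE, n = 2 per group). These 3 were higher in both mutants than in both wild-types, which chance gives for 16.7% of genes, and the groups overlapped for Per1, Mt1, Zbtb16, Pdk4 and Sult1a1. None of the 8 passed the limma test over all genes, with an adjusted p of 0.989 for Plin4, Mt2 and Klf9.

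Choroid plexus markers differed between the libraries of each group, which share a genotype, and no biological explanation was tested. Depth is argued against, since before scaling the markers' median log2 difference exceeded the log2 depth ratio by 2.96 or more in both groups (SD over markers 0.822 in wild-type). Tissue carried over into wild-type 11 and mutant 38 is a candidate explanation, as the excess in mutant 38 was in nearly one proportion to that in wild-type 11 over the 17 markers (SD of the log2 ratio 0.266). Of the 3 ways to split the libraries evenly, the labelled one gave 1 changed gene, the third 0 and the one along these pairs 91, a structure that the markers, 17 of the 91, were themselves used to draw, and 2 against 2 is too few for a share under 0.05. With the choroid plexus level as covariate the labelled split gave 80 and the third 2.

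Apold1 rose, and Cyr61, Dusp1 and Btg2 were higher in both mutants without passing over all genes, while the immediate early list as a whole did not pass (camera adjusted p = 0.604). More vessel cells are argued against by 11 endothelial markers, with a median log2 fold change of 0.031 (SD 0.178). For more neuronal activity, 13 activity-regulated genes had a median of -0.20 (SD 0.364). These 13 were picked from the immediate early list after the result was seen, without the higher Cyr61, Dusp1 and Btg2. Their median therefore cannot decide whether neuronal activity differed. Choroid plexus carry-over is argued against by its 17 markers, for which the lower mutant library differed from the higher wild-type one by a median log2 of -3.25 (SD 1.05). A stress hormone response, from handling or from the mutation, may contribute, but was not settled. The 8 glucocorticoid-induced genes had a median of 0.15, at the 98.9th percentile of 10000 random lists matched on mean expression. Random lists do not carry the correlation of co-regulated genes or the spread between libraries, so the percentile may overstate the shift. Handling and genotype were not separated, and a direct effect of the mutation stays open and untested.

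With the preset correlation the oligodendrocyte, thalamus and blood lists rose and the dentate list fell, and with an estimated correlation each had a camera adjusted p = 0.913. That value cannot decide whether the lists changed, since p also rose for lists whose estimate lay below the preset correlation. Wild-type 73 may account for much of the oligodendrocyte part, whose median went from 0.44 to 0.20 without it. Mutant 38 may account for the thalamus part, whose median was 0.026 without it, although Slc17a6 was high in mutant 39 too, at 783 scaled read equivalents. The 3 higher lists gave 2 orders of the libraries, which differed only in the place of the mutants. Blood genes were higher in mutant 39 than in mutant 38 by 0.24 (SD 0.0871 over genes), and oligodendrocyte genes differed by -0.16 (SD 0.101). These are single libraries with an SD over genes, so the orders cannot decide whether a shared difference in dissection lay behind all 3 lists. A dissection difference behind the thalamus and oligodendrocyte lists alone, which gave the same order, stays open too, as does the mutation.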
